A study of Caenorhabditis elegans with 12 samples.

How the data were processed

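Small RNA libraries were made from whole Caenorhabditis elegans of 4 genotypes, with 3 libraries each. Per the labels, the strains were wild type (N2), the mbl-1(tm1563) mutant, and a pair of edited lines that express only a short or only a long isoform of MBL-1, the worm Muscleblind RNA-binding protein. The sample titles call the edited lines mbl-1(syb4318) and mbl-1(syb4345), named here in no order of isoform length. Animals were synchronized by bleaching, grown on OP50 bacteria at 20 °C and collected as L4 larvae, and the libraries held adaptor-ligated inserts of 18 to 40 nt, read from 1 end over 50 nt. The deposited count columns of the isoform lines carry the codes CR_MED and CR_SH, and the authors' comparison tables use the codes ME and SH. That CR_MED is ME and CR_SH is SH was inferred from the likeness of the codes. Across the listed features, the log2 ratios of the group means in the authors' deposited tables correlated with those from the count columns at r = 0.9998 for ME and CR_MED (41 features) and 0.9996 for SH and CR_SH (12 features), and at 0.481 and 0.855 with the codes exchanged. No label ties a code to a strain or to the short or long isoform, so the groups are called the ME line and the SH line, and no isoform length is assigned to either. The tm1563 columns were matched by inference: they carry the name of the mbl-1 gene with no line code. The sample titles call all 3 mutant strains mbl-1 mutants, while the series' design text names an mbl-1 mutant beside the 2 mutants that express an isoform. The labels describe the 3 libraries of each genotype as biological replicates.

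The authors deposited a table of read counts per mature miRNA arm, as whole numbers with no normalization, for 370 features with a miRBase name and 101 predicted miRNAs without one. Per the submitters' processing notes, Bowtie, DESeq2 and the genome build WBcel235 were used, with no versions. The mismatches allowed, the treatment of reads that map to several places and the counting program are not given in the sources used here. Arms with near-identical sequences, such as miR-44-3p and miR-45-3p, the miR-58a-3p, miR-80-3p, miR-81-3p and miR-82-3p group, the members of the mir-35, mir-51 and miR-1829 groups, and miR-789 with its copies, may share reads, so their individual values are uncertain. The authors' 3 comparison tables against wild type hold a normalized mean read count per group (a signal, per the file headers), a log2 fold change and a p-value with its adjusted value, and list only features that passed the authors' threshold. The columns of the deposited count table that hold per-million values were not used, and 0 of its library columns were left unmapped.

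Totals lay between 6946205 and 12053039 counts per library. A feature with 3 counts, taken as the floor, stands at 0.249 CPM in the deepest library and 0.432 CPM in the shallowest. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Features were kept for testing where edgeR's filterByExpr passed them (minimum count 10, minimum total 15). This left 250 features, and the 221 others held 0.00490% of all counts. CPM values use TMM-scaled library sizes.

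The 12 libraries entered a single edgeR quasi-likelihood fit (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3, robust) with 1 mean per genotype and no block. Each P was adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, and intervals are at 95%. The 6 comparisons were each mutant line against wild type and each pair of mutant lines. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the lists within a comparison. They comprised 11 lists of named miRNAs: the let-7 family, late larval timing miRNAs, the mir-35, mir-44, mir-51, mir-58 and mir-64 families, neuron-enriched miRNAs, miRNAs of other tissues, lifespan and stress miRNAs, and mirtrons. A further 2 lists followed a rule: the minor arm of each precursor with both arms in the table, taken as the arm with the lower mean count, and the predicted miRNAs without a miRBase name. The lists overlap. By the rule miR-41-3p, miR-795-5p and miR-239a-5p count as minor arms, and they are also in the mir-35, let-7 and lifespan and stress lists, respectively.

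Named miRNAs followed a rule. Where 24 or fewer passed the threshold, all were named. Otherwise up to 12 rises and 12 falls were eligible, ranked by log2 fold change, among those whose 3 libraries of one group all lay on one side of the other group's. In addition let-7-5p, lin-4-5p, miR-1-3p, miR-124-3p, miR-71-5p, the 5 most abundant features and up to 4 members per list with the smallest p were eligible in each comparison with wild type. By the same rule a paragraph may leave out eligible miRNAs whose values add nothing and give their count. The grouping, lists, naming rule, tests of the comparisons and alternatives were chosen before the data were examined, except the removal of wild-type library 1 with ME library 1 and the tests that the additional observations name as chosen after the results were seen. A test of a flagged pattern could be framed only once that pattern was seen.

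Comparisons that share the wild-type libraries were set beside simulated values, in 100 draws for correlations and 20 refits for overlaps of calls. There all 12 libraries were simulated with no group changed, and the comparisons shared the simulated wild-type libraries. The procedure was tested on 5 simulated sets for tm1563 against wild type, over 250 features with 40 changed in each. It recovered 17.1% of the features changed 1.5-fold, 81.3% of those changed 2-fold and 95.3% of those changed 4-fold, and 4.58% of its calls were false. Each feature was drawn independently, with the dispersions fitted to the real data. No library was made to stand apart, so the rates in the real comparisons may be worse. Alternatives were RLE size factors, scaling by library totals, no filter, annotated features only, the 3 most abundant features left out, the 2 compared groups fitted alone, DESeq2 1.42.0, a replicate block for tm1563 against wild type, each library left out in turn, and, for lists, camera with an estimated correlation and fry. Coordinates are those of the precursor genes in the WBcel235 annotation, which matched 368 of the 370 named features. The transcript of mbl-1 itself, on chromosome X from 16978608 to 17010302 in WBcel235, is too long for these libraries and was not measured, so the target gene could not be used to check the labels.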

Results

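Small RNA was counted in 12 libraries of whole L4 larvae, 3 each from wild type, the mbl-1(tm1563) mutant, the ME line and the SH line, to ask how miRNA levels depend on MBL-1 and its isoforms. The 3 wild-type libraries held 8493518, 9784205 and 12053039 counts and the tm1563 libraries 10764528, 7890851 and 7388114. The ME libraries held 8066278, 7886761 and 6946205 counts and the SH libraries 7512188, 7215341 and 7099111. In every genotype a few miRNAs took most of the counts. The muscle miRNA miR-1-3p made up 20.9% ± 1.44 (SD, n = 3) of the wild-type counts, and together with miR-70-3p, miR-58a-3p, miR-82-3p and miR-44-3p it made up 61.8% ± 5.93 in wild type. The share of these 5 averaged 57.4% ± 3.51 in tm1563 and 59.7% ± 3.68 in the SH line (SD, n = 3 each), and that of the ME line lay between those of the SH line and wild type. A pair of libraries stood apart. In wild-type library 1, 326 features were detected, against 365 to 400 in each of the other 11 libraries, and its TMM factor was 0.788. In ME library 1, miR-70-3p took 28.8% and miR-1-3p 12.5% of the counts. The biological coefficient of variation over the fit was 22.7%.

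The tm1563 mutant was compared with wild type to ask which miRNAs differ when mbl-1 carries this allele. Relative to wild type, miR-245-3p rose 3.69-fold, from 32.9 ± 4.88 to 121 ± 17.7 CPM (mean ± SD, n = 3; log2 fold change 1.88, SE 0.21, edgeR adjusted p = 3.39e-05). Also higher were miR-90-3p, from 603 ± 46.2 to 1576 ± 448 CPM (log2 fold change 1.39, SE 0.21), miR-790-5p of the neuron-enriched list, from 125 ± 39.5 to 314 ± 17.5 CPM (1.33, SE 0.27), and miR-251, from 2.39 ± 0.444 to 7.96 ± 3.10 CPM (1.74, SE 0.35), the last at very low counts. The RDE-1-bound miRNA miR-243-3p rose from 236 ± 28.6 to 461 ± 58.5 CPM, and miR-57-5p, which acts in posterior cell fate, from 8723 ± 495 to 15536 ± 933 CPM. The deepest falls among miRNAs above 20 CPM were those of miR-246-5p, from 59.0 ± 5.42 to 28.5 ± 3.67 CPM, and miR-51-3p, from 73.8 ± 8.37 to 37.3 ± 6.10 CPM, with log2 fold changes of -1.05 (SE 0.24) and -0.99 (SE 0.20).

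Smaller rises were measured for miR-230-3p, miR-53-5p, miR-1830-5p, miR-242, miR-356b-3p, miR-234-3p and miR-56-3p, at log2 fold changes between 0.59 and 0.86. The falls included miR-1829b-3p (-1.28, SE 0.37) and miR-1829b-5p (-0.92), whose reads may be shared with the other miR-1829 copies, and miR-71-3p (-0.79, SE 0.18), the minor arm of the lifespan miRNA miR-71. Also lower were miR-82-5p, miR-240-5p, miR-785-3p, miR-246-3p, miR-59-3p and miR-229-3p, at log2 fold changes from -0.67 to -0.57, and 1 predicted miRNA without a registered name. The developmental timing miRNAs let-7-5p and lin-4-5p had log2 fold changes of 0.12 (95% interval -0.18 to 0.43) and 0.24 (-0.38 to 0.87) and did not pass the test. The same held for miR-1-3p at -0.32 (-0.85 to 0.21), miR-71-5p at -0.23 (-0.70 to 0.24) and the sensory neuron miRNA miR-124-3p at 0.01 (-1.01 to 1.02), the last counted at under 4 CPM.

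**Figure D1:**
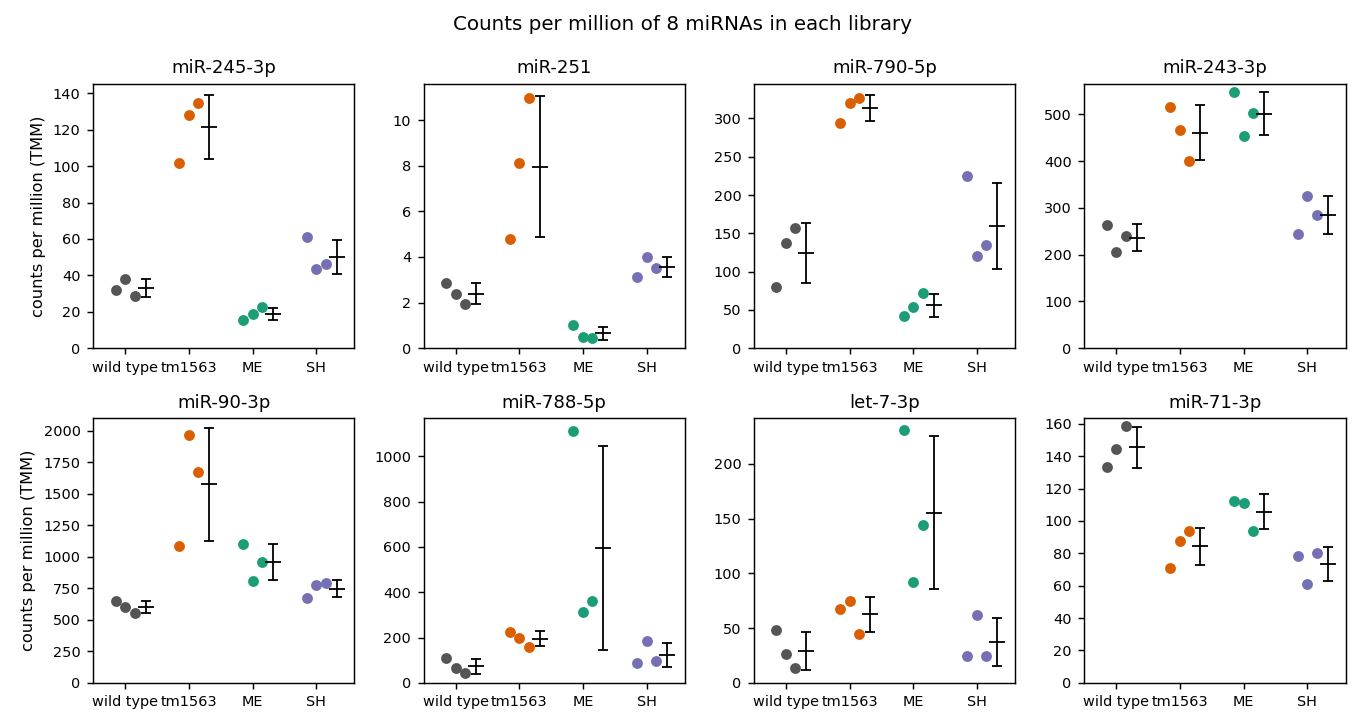
TMM-scaled counts (CPM, linear axes from 0) of 8 miRNAs in the 12 libraries, with 1 point per library and the mean ± SD of each genotype (n = 3). The 3 tm1563 libraries lie above the 3 wild-type libraries for miR-245-3p, miR-251 and miR-790-5p, and the 3 ME libraries lie below them.

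By list, the 6 measured members of the broadly expressed mir-51 family all had positive log2 fold changes in tm1563, with a median of 0.47, and the sign held under each scaling tried. Of these, miR-53-5p and miR-56-3p rose over all features tested, and 3 rose adjusted over the list alone, the third being miR-52-5p at 0.66. The list itself missed the camera threshold (adjusted p = 0.0530, and adjusted p = 0.657 with an estimated correlation). Of the 5 neuron-enriched miRNAs, 1 rose over all features tested and 2 adjusted over the list alone, miR-790-5p and miR-791-3p (1.74), with a camera adjusted p of 0.174. Of the 80 minor arms, 1 rose and 6 fell, both over all features tested and adjusted over the list alone, with an adjusted p of 0.0530. The gonad miRNA miR-246-3p fell, the only call in the lifespan and stress list (8 members) and in the list of other tissues (4 members), also adjusted over the list alone. Among the 15 tested predicted miRNAs without a name 1 fell, also adjusted over the list alone. The late larval, let-7, mir-35, mir-44, mir-58 and mir-64 families and the mirtrons held 0 calls by edgeR among their 34 members, with 6 at an unadjusted p under 0.05 and 2 calls by DESeq2, and 1 fall in the mir-44 family adjusted over the list alone. No list passed camera in this comparison: 3 had an unadjusted p under 0.05, and 0 passed by fry or with an estimated correlation. Without wild-type library 1 the minor arms (down) and the neuron-enriched miRNAs (up) passed, without wild-type library 3 or tm1563 library 2 the minor arms, and without tm1563 library 1 the mir-51 family.

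In all, edgeR called 25 of the 250 features in tm1563 against wild type, 13 higher and 12 lower, with 64 at an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 34.4% of the features, where chance gives 10%. The split depended on scaling, at 11 higher and 18 lower with RLE size factors, 14 higher and 1 lower with library totals, and 16 higher and 22 lower by DESeq2. Library totals moved the median log2 fold change of all features from 0.03 to 0.15, and RLE size factors moved it to -0.05. Without wild-type library 1, 2 or 3 the number of calls was 16, 14 or 10, and without tm1563 library 1, 2 or 3 it was 5, 10 or 14. The calls of miR-245-3p, miR-251, miR-90-3p, miR-790-5p and miR-243-3p were kept in all 6 of these fits, and the other 20 were each lost in at least 1. The authors' deposited table for this comparison lists 51 features, 24 higher and 27 lower, and holds all 25 called here with the same direction.

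The ME line, which makes 1 class of MBL-1 isoform, differed from wild type in several minor arms, the less abundant strands of miRNA precursors. The minor arm miR-788-5p rose from 73.9 ± 33.1 to 596 ± 449 CPM (log2 fold change 3.02, SE 0.53, edgeR adjusted p = 0.00417), with ME library 1 at 1114 CPM and the others at 315 and 359. The minor arm of let-7, let-7-3p, rose from 29.3 ± 17.3 to 155 ± 70.1 CPM (2.42, SE 0.52), and miR-44-5p from 11.2 ± 0.511 to 41.6 ± 20.7 CPM (1.89, SE 0.34). In contrast, miR-252-5p fell from 48.5 ± 6.61 to 16.8 ± 4.54 CPM (-1.53, SE 0.25, adjusted p = 0.00202), and miR-790-5p from 125 to 55.9 CPM (-1.16, SE 0.27). Also lower were miR-245-3p (-0.80, SE 0.21) and miR-251 (-1.83, SE 0.45, at under 3 CPM in both groups), so that these and miR-790-5p were higher than wild type in tm1563 and lower in the ME line. The rises of miR-788-5p and let-7-3p may not be particular to the ME line. In tm1563 their log2 fold changes were 1.40 and 1.11, which did not pass here (edgeR adjusted p = 0.0958 and 0.194), and the authors' deposited table for tm1563 lists both as higher.

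Among abundant miRNAs, miR-246-3p fell from 4562 ± 296 to 2274 ± 599 CPM (edgeR adjusted p = 0.00382), and miR-359 from 1978 ± 335 to 999 ± 276 CPM (-0.99, SE 0.20). Also lower were miR-76-3p (-1.29, SE 0.24), miR-1817 (-1.06, SE 0.21), miR-39-5p (-1.01), miR-40-5p (-0.95), miR-82-3p (-0.83), miR-795-3p (-0.77), miR-81-3p (-0.60) and miR-61-3p (-0.59). The rises also comprised miR-243-3p (1.09, SE 0.17), miR-233-5p (1.36, SE 0.44), miR-49-5p (1.05), miR-243-5p (0.97), miR-83-5p (0.91), miR-58a-5p (0.86), miR-1830-5p (0.84), miR-70-5p (0.84), miR-57-5p (0.83), miR-230-3p (0.80) and miR-90-3p (0.66). For let-7-5p the log2 fold change was 0.06 (95% interval -0.25 to 0.36), for lin-4-5p -0.09 (-0.71 to 0.54) and for miR-1-3p -0.22 (-0.75 to 0.31), and none of these passed the test, nor did miR-71-5p at 0.10 (-0.37 to 0.57) or miR-124-3p at -0.26 (-1.36 to 0.83).

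Of the 80 minor arms, 12 rose and 2 fell in the ME line over all features tested, and 14 rose and 5 fell adjusted over the list alone, with a median log2 fold change of 0.12 and a camera adjusted p of 0.181. In the mir-58 (bantam) family, whose members may share reads, miR-81-3p and miR-82-3p were the 2 of 5 that fell, also adjusted over the list alone, with a median of -0.39. All 5 neuron-enriched miRNAs had negative log2 fold changes, with a median of -0.58 and a camera adjusted p of 0.181, and 1, miR-790-5p, fell both over all features tested and adjusted over the list alone. The lifespan and stress list and the list of other tissues each held 1 fall, miR-246-3p, also adjusted over the list alone. The mir-44 family held 1 fall, miR-61-3p, and 1 rise besides it adjusted over the list alone. Its median was 0.03 and its camera direction was down, and the median turned negative with RLE size factors. Among the predicted miRNAs without a name 1 rose, and 0 adjusted over the list alone. The late larval, let-7, mir-35, mir-51 and mir-64 families and the mirtrons held 0 calls by edgeR among 32 members, or adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 3 calls by DESeq2. No list passed camera: 3 had an unadjusted p under 0.05, and 0 passed by fry or with an estimated correlation.

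By edgeR, 34 of the 250 features differed between the ME line and wild type, 19 higher and 15 lower, with 81 at an unadjusted p under 0.05 and 34.0% of features without overlap between the groups (10% by chance). With RLE size factors 15 were higher and 22 lower, with library totals 19 and 9, and by DESeq2 18 and 28. The median of all features moved from 0.07 to -0.04 with RLE size factors and to 0.13 with library totals. Without ME library 1 there were 10 calls, without ME library 3 there were 22 and without wild-type library 3 there were 19. Without wild-type library 1 and ME library 1 together, a setting chosen after seeing the data, there were 14. With single libraries left out, 10 calls were kept in all 6 fits, among them miR-788-5p, let-7-3p, miR-44-5p, miR-252-5p, miR-251, miR-243-3p, miR-246-3p and miR-359. Without ME library 1 the edgeR adjusted p of miR-790-5p was 0.0689 and that of miR-245-3p 0.0866, and without wild-type library 2 that of miR-245-3p was 0.0789. The authors' deposited table for this line lists 41 features, 16 higher and 25 lower, which include 30 of the 34 called here.

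**Figure D2:**
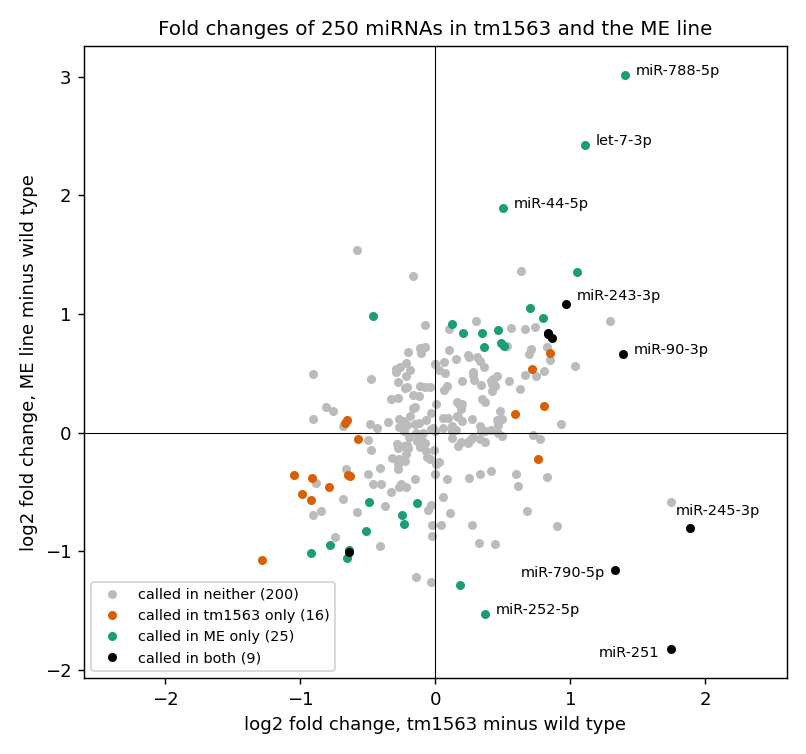
Log2 fold change against wild type in tm1563 (horizontal axis) and in the ME line (vertical axis) for the 250 features tested, with 1 point per feature, coloured by whether edgeR called it in tm1563, in the ME line, in both or in neither. Of the 9 called in both, miR-245-3p, miR-251 and miR-790-5p lie at the lower right, higher in tm1563 and lower in the ME line.

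The SH line differed from wild type in 5 miRNAs, and all 5 were minor arms and lower. The largest fall was that of miR-238-5p, from 9.23 ± 2.65 to 3.25 ± 0.588 CPM (mean ± SD, n = 3; log2 fold change -1.49, SE 0.30, edgeR adjusted p = 0.00881). It was followed by miR-246-5p (-1.23, SE 0.24), miR-71-3p (-0.99, SE 0.18, to 73.4 ± 10.6 CPM from 145 ± 12.7), miR-229-3p (-0.85, SE 0.17) and miR-82-5p (-0.79, SE 0.18). The major arms let-7-5p at -0.11 (95% interval -0.42 to 0.19), lin-4-5p at -0.02 (-0.64 to 0.61), miR-1-3p at -0.13 (-0.66 to 0.40) and miR-71-5p at -0.04 (-0.51 to 0.42) did not pass the test, and neither did miR-124-3p at -0.84 (-1.98 to 0.30).

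As a list, the 80 minor arms were lower in the SH line with a median log2 fold change of -0.20, a sign that held under each scaling, and a camera adjusted p of 4.54e-04, or adjusted p = 0.297 with an estimated correlation. Of these, 5 fell over all features tested and 9 adjusted over the list alone. The other 12 lists, from the let-7 and mir-35 families to the neuron-enriched miRNAs, mirtrons and predicted miRNAs, held 0 calls by edgeR among 70 members, also adjusted over each list alone, with 7 at an unadjusted p under 0.05 and 0 calls by DESeq2. Their camera adjusted p values lay between 0.305 and 0.924.

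The 5 calls stood beside 36 features at an unadjusted p under 0.05 and 17.2% of features without overlap (10% by chance). With library totals edgeR made 0 calls, with 32 features at an unadjusted p under 0.05, and with these 2 groups fitted alone it made 0, with 31. DESeq2 made 10, 1 higher and 9 lower. Without SH library 1, 2 or 3 there were 3, 2 or 8 calls, and without wild-type library 3 there were 3. The calls of miR-246-5p and miR-71-3p were kept in all 6 of these fits. The authors' deposited table lists 12 features for this line, 2 higher and 10 lower, and holds all 5 called here.

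The ME and SH lines, which make different MBL-1 isoforms, were also compared with each other. In the ME line miR-788-5p was higher than in the SH line by a log2 fold change of 2.28 (SE 0.51, edgeR adjusted p = 0.0125), let-7-3p by 2.07 (SE 0.51) and miR-44-5p by 1.72 (SE 0.34, adjusted p = 0.00335). Minor arms higher by about 1 or more also included miR-83-5p (1.40, SE 0.26), miR-67-5p (1.40), miR-237-3p (1.09) and miR-61-5p (1.04, SE 0.19). Lower in the ME line were miR-251 (-2.41, SE 0.44), miR-252-5p (-1.78, SE 0.25, adjusted p = 7.48e-04), miR-790-5p (-1.52, SE 0.28), miR-245-3p (-1.41, SE 0.21), miR-358-5p (-1.15), miR-359 (-1.07), miR-76-3p (-1.05), miR-246-3p (-0.92) and miR-1817 (-0.74).

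Of the 80 minor arms, 20 were higher and 0 lower in the ME line over all features tested, and 27 were higher and 1 lower adjusted over the list alone. Of the 80, 35 had an unadjusted p under 0.05 and DESeq2 called 19. The median was 0.51, or 0.35 with RLE size factors, with a camera adjusted p of 2.17e-06 and adjusted p = 0.110 with an estimated correlation. In each precursor the minor arm can be set against its major arm: over 80 precursors the median difference of their log2 fold changes was 0.41, positive for 61 and negative for 19 (sign test across precursors, which are not independent replicates, adjusted p = 8.20e-06 over 6 comparisons). Per library, the median log2 ratio of minor to major arm, centred over the 12 libraries, was 0.25 ± 0.06 in the ME line, -0.17 ± 0.09 in the SH line, 0.07 ± 0.05 in wild type and -0.07 ± 0.07 in tm1563 (mean ± SD, n = 3 each). The ME and SH libraries did not overlap (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). In the neuron-enriched list 1 member, miR-790-5p, was lower, and miR-246-3p was the 1 member lower in the lifespan and stress list and in the list of other tissues, each also adjusted over the list alone. The remaining 9 lists held 0 calls by edgeR among 55 members, with 2 at an unadjusted p under 0.05 and 3 calls by DESeq2.

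**Figure D3:**
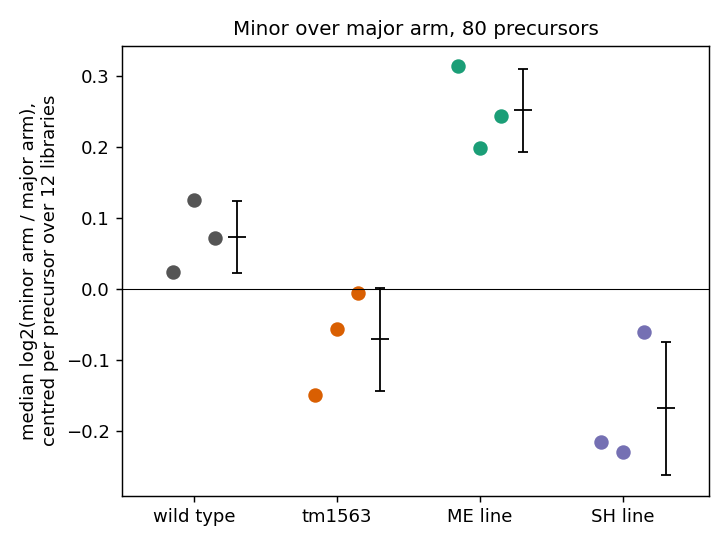
Median log2 ratio of minor to major arm over 80 precursors in each of the 12 libraries, each precursor centred on its mean over libraries, with the mean ± SD of each genotype (n = 3). The 3 ME libraries lie at 0.20 to 0.31 and the 3 SH libraries at -0.23 to -0.06.

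By edgeR, 36 features differed between the ME and SH lines, 27 higher and 9 lower in the ME line, with 66 at an unadjusted p under 0.05 and 30.4% without overlap (10% by chance). The excess of higher calls was scaling-dependent, at 12 higher and 12 lower with RLE size factors, which moved the median of all features from 0.13 to -0.03, at 10 and 8 with library totals and at 22 and 20 by DESeq2. Without ME library 1 or 3 there were 21 or 17 calls, and without SH library 1 there were 12. Kept in all 6 fits with 1 library left out were 11 calls, among them miR-251, miR-252-5p, miR-245-3p, miR-790-5p, miR-44-5p, miR-83-5p and miR-61-5p.

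Between tm1563 and the ME line the largest differences were those of miR-251 (log2 fold change 3.57, SE 0.42, at very low counts), miR-245-3p (2.69, SE 0.22, edgeR adjusted p = 4.28e-07) and miR-790-5p (2.49, SE 0.29), all higher in tm1563. The sensory neuron miRNA miR-791-3p (2.32, SE 0.63, at under 4 CPM), miR-252-5p (1.90, SE 0.25), miR-76-3p (1.47), the let-7 family member miR-795-5p (1.38), miR-790-3p (1.34), miR-358-5p (1.06), miR-786-3p (1.04), miR-356b-3p (0.99), miR-90-3p (0.72), the abundant miR-72-5p (0.68) and miR-1821-3p (0.63) were also higher. Lower in tm1563 were miR-42-5p (-2.12, SE 0.53), miR-237-3p (-1.45, SE 0.29), miR-44-5p (-1.40, SE 0.33), miR-81-5p (-1.03), miR-788-3p (-0.80), miR-5592-3p (-0.80), miR-240-5p (-0.76), miR-82-5p (-0.75), miR-61-5p (-0.71) and miR-80-5p (-0.55). Of the 5 neuron-enriched miRNAs 3 were higher in tm1563, over all features tested and adjusted over the list alone (median 0.75, camera adjusted p = 0.00101, and adjusted p = 0.107 with an estimated correlation). Of the 80 minor arms 2 were higher and 7 lower, and 2 and 17 adjusted over the list alone (median -0.32, camera adjusted p = 7.79e-05, and adjusted p = 0.107 with an estimated correlation). In all 24 features differed, 14 higher and 10 lower in tm1563, with 68 at an unadjusted p under 0.05. With library totals 11 were higher and 4 lower, and by DESeq2 17 and 15. Without tm1563 library 1, 2 or 3 there were 15, 14 or 13 calls. With single libraries left out, 8 of the 24 calls were kept in all fits. Among the neuron-enriched calls only that of miR-790-5p was kept.

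Between tm1563 and the SH line, miR-791-3p (2.68, SE 0.65, at under 4 CPM), miR-245-3p (1.27, SE 0.21, edgeR adjusted p = 0.00354), miR-90-3p (1.08, SE 0.20) and miR-243-3p (0.70) were higher in tm1563 and miR-51-3p (-0.87) was lower. These 5 were all the calls, with 43 features at an unadjusted p under 0.05 and 13 calls by DESeq2, 6 higher and 7 lower. With RLE size factors 3 were higher and 3 lower, and with library totals 4 were higher and 0 lower. Without tm1563 library 3 edgeR made 0 calls, with 23 at an unadjusted p under 0.05, and 2 without any other single library of these groups. The neuron-enriched list was higher in tm1563 (median 0.84, 1 of 5 over all features tested and 3 adjusted over the list alone, camera adjusted p = 0.0215, and adjusted p = 0.336 with an estimated correlation). Its members miR-791-3p, miR-124-3p and lsy-6-3p were counted at under 4 CPM in tm1563.

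Several changes against wild type were shared between lines. Both tm1563 and the ME line had higher miR-243-3p, miR-90-3p, miR-57-5p, miR-230-3p and miR-1830-5p, 5 shared rises where independent lists would give 0.988, and lower miR-246-3p, 1 shared fall where independent lists would give 0.720. They had 3 opposite changes, those of miR-245-3p, miR-251 and miR-790-5p, where independent lists would give 1.69. Both tm1563 and the SH line had lower miR-71-3p, miR-246-5p, miR-229-3p and miR-82-5p, 4 shared falls where independent lists would give 0.240. The ME and SH lines shared 0 calls, where independent lists would give 0.300. With all 12 libraries simulated and no group changed, 0.05 calls or fewer were shared on average. Few calls can be expected where no group changes, so this does not show how far the real wild-type libraries make the called lists overlap. Across the 250 features, which are not independent replicates, the log2 fold changes of tm1563 and the SH line correlated at r = 0.65, against 0.48 simulated with no effect, with a covariance of 0.139 against 0.0495. For tm1563 and the ME line r was 0.38 against 0.50, with a covariance of 0.117 against 0.0521. For the ME and SH lines r was 0.40 against 0.48, with a covariance of 0.0993 against 0.0507. The 3 wild-type libraries are too few to split, so part of each excess may come from the shared controls.

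In the WBcel235 annotation the precursor of miR-245 lies on chromosome I from 7887371 to 7887467 and that of miR-251 on X from 11004728 to 11004824. That of miR-790 lies on IV from 5566422 to 5566491 and that of miR-788 on X from 8485294 to 8485371. All lie outside annotated protein-coding genes, and overlap with other kinds of gene was not checked. The precursors of miR-246 (IV, 10940134 to 10940230), miR-238 (III, 8867328 to 8867425), miR-359 (X, 3004291 to 3004400) and miR-44 (II, 11890023 to 11890118) also lie outside annotated protein-coding genes. Those of miR-90 (III, 8873987 to 8874084) and miR-243 (IV, 4450779 to 4450876) lie in introns of K01F9.2 and R08C7.12, that of miR-71 (I, 9379927 to 9380020) in an intron of ppfr-1 and that of miR-82 (X, 2435258 to 2435354) in an intron of gid-2, each on the strand of the host gene. The precursor of miR-252 (II, 11446863 to 11446960) lies within an intron of W02B12.13 on the opposite strand.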

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

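The counts over other splits of the libraries, the tests of a single library, the removal of wild-type library 1 with ME library 1 and the test of the neuron share were chosen after the results were seen. The fits with a single library left out were themselves planned, except for the difference between minor and major arms. For the minor arms, predictions for the matched lists and the major arms were written before those tests were run. The pattern they address had to be seen first.

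The mutant lines differed from each other in direct tests of their changes against wild type. These called 36 miRNAs between the ME and SH lines, 24 between tm1563 and the ME line and 5 between tm1563 and the SH line. For each of the 6 comparisons the 6 libraries were regrouped in every way into 3 and 3. Of the 10 splits, 1, the real one, gave as many calls in each comparison, and 10 splits allow no share under 0.1. The real and highest other counts were 25 and 0 for tm1563 against wild type, 34 and 0 for the ME line against wild type, 5 and 0 for the SH line against wild type, 36 and 6 for the ME against the SH line, 24 and 0 for tm1563 against the ME line, and 5 and 0 for tm1563 against the SH line.

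The miRNAs miR-251, miR-245-3p and miR-790-5p were higher than wild type in tm1563 and lower in the ME line, and the tm1563 minus ME log2 fold changes were 3.57, 2.69 and 2.49. The miRNAs were chosen for these opposite calls, so the size of that difference is no separate evidence, and wild-type libraries that lie apart as a group stay open as part of either change. For the difference between tm1563 and the ME line, the highest edgeR adjusted p of the 3 with any 1 tm1563 or ME library left out was 5.19e-04. The difference thus did not rest on any 1 of these libraries. Selection for opposite calls makes such a result likely, so it is only weak evidence. The fall below wild type in the ME line kept its direction with any 1 wild-type or ME library left out. The log2 fold changes were then -0.68 to -1.04 for miR-245-3p, -0.96 to -1.49 for miR-790-5p and -1.62 to -2.31 for miR-251. Their upper 95% bounds were -0.18 or lower, not adjusted for the features tested. This bound replaced one on the edgeR adjusted p, which reached 0.0866, after the values were seen. The miRNAs were also selected for being called, so this is only weak evidence against a single library as the whole cause. The calls are less firm than the folds. That of miR-251, counted at 0.646 CPM in the ME line, held in all 6 fits (highest adjusted p = 0.0489). Without ME library 1, where the calls over all features went from 34 to 10, the values were -0.71 (SE 0.23, adjusted p = 0.0866, from -0.80, SE 0.21) for miR-245-3p and -1.03 (SE 0.30, adjusted p = 0.0689, from -1.16, SE 0.27) for miR-790-5p. For miR-245-3p the adjusted p was 0.0789 without wild-type library 2 (-0.68, SE 0.23) and 0.118 without wild-type library 1 and ME library 1 together. A larger share of neurons in the tm1563 RNA stays open. Of the 3 miRNAs, miR-790-5p alone is on the neuron-enriched list. Of the list's 4 other members, 3 had upper 95% bounds under the smallest difference to be explained, 2.49 (SE 0.29), whose own error was left aside. They were miR-1821-3p (0.63, bound 1.00), lsy-6-3p (0.75, bound 1.89) and miR-124-3p (0.27, bound 1.35), which would go against a larger share of neurons as the whole cause. However, 1 of these, miR-1821-3p, was counted at 10 CPM or more and the others at under 4 CPM, and miR-791-3p, also at under 4 CPM, differed by 2.32 (bound 3.65) as a larger share would have it. Strain background and library batch cannot be told apart from genotype in this design, so an effect of the mbl-1 alleles may be one explanation among these.

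Minor arms were higher in the ME than in the SH line, with a median log2 fold change of 0.51 over 80 arms, or 0.35 with RLE size factors and 0.46 with library totals. The list passed camera with the preset correlation (adjusted p = 2.17e-06) and fry (adjusted p = 0.00329), and missed the threshold in camera with an estimated one (adjusted p = 0.110). A bias of weakly counted features is argued against by 10000 lists of other features matched on abundance, whose medians centred on -0.02 with 95% between -0.17 and 0.19, which put the minor arms at percentile 100. Features of the same libraries are not independent replicates, so that spread may be too narrow and the percentile is not a p-value. A higher output of whole precursors is argued against by the minor minus major difference of 0.41 within precursors, with a major-arm median of -0.01. With any single library left out that difference was 0.395 or more. A difference in strand retention between the lines may be a candidate explanation and was not tested, and strain background, library batch and RNA handling stay open because they cannot be told apart from genotype.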

How the results depend on the processing

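All alternatives here were planned except the removal of wild-type library 1 with ME library 1, which was chosen after the results were seen. No call reversed its direction in any alternative run on the named miRNAs. Where a count below left the range of 1.5 times the main one, the cause was not tested, beyond there being fewer libraries where some were left out. For tm1563 against wild type (25 calls) scaling by library totals gave 15, the 2 groups fitted alone 41 and DESeq2 38. For the SH line against wild type (5) library totals gave 0 and the 2 groups alone 0 by edgeR (32 and 31 features at an unadjusted p under 0.05), and DESeq2 10. Library totals gave 18 for the ME against the SH line (36) and 15 for tm1563 against the ME line (24), for which annotated features only gave 40 and leaving out the 3 most abundant features 38. For tm1563 against the SH line (5) the 2 groups alone gave 8 and DESeq2 13. Without wild-type library 1 and ME library 1 there were 14 calls for the ME line (34) and 9 for the SH line against wild type. With 1 library left out the ranges were 5 to 16 for tm1563, 10 to 39 for the ME line and 2 to 8 for the SH line against wild type, 12 to 36 for ME against SH, 13 to 35 for tm1563 against ME and 0 to 2 for tm1563 against SH.

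For lists, tm1563 against wild type (0) gave 1 with no filter, 3 without wild-type library 1 and ME library 1, and 0 to 2 with 1 library left out. The list called in the SH line against wild type (1) was lost with an estimated correlation (0) and by fry (0, with 2 lists at an unadjusted p under 0.05), and that in the ME against the SH line (1) was lost with an estimated correlation (0, with 1 at an unadjusted p under 0.05) and kept by fry. By fry the let-7 family also passed in tm1563 against the ME line (median log2 fold change 0.17, adjusted p = 0.00529) and against the SH line (median 0.13, adjusted p = 0.0146). Camera called it in neither (adjusted p = 0.449 and 0.401). Over the 86 features of at least 100 CPM the covariance of fold changes was 0.155 for tm1563 and ME (0.0360 simulated with no effect, r = 0.62 against 0.50), 0.108 for tm1563 and SH (0.0342, r = 0.68 against 0.48) and 0.0821 for ME and SH (0.0360, r = 0.46 against 0.50). The last lay within the simulated draws, which reached 0.0907. Of the named calls, 18 of 25 for tm1563, 8 of 26 for ME, 5 of 5 for SH against wild type and 8 of 21 for ME against SH were lost in at least 1 scaling, filter or block alternative.

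With the replicate number as a block, tm1563 against wild type gave 9 calls. The deviations of same-numbered libraries correlated at -0.01, 0.07 and 0.10, and no wild-type library correlated best with its own number. These 3 values were not tested and cannot show whether the numbers mark a shared batch. For the other comparisons, No paired analysis was possible because the ME and SH columns match no single labelled sample, so the numbers in their names are not known to be the labels' replicate numbers, and the planned block was not run. Depth limits miR-251, miR-791-3p and miR-124-3p, which were counted at a few CPM or less.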

Other observations

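The tests of arms beyond the ME and SH lines and the tests on wild-type library 1 were chosen after the results were seen. For the test with reads thinned to equal depth, the prediction was written before that test was run. The low number of detected features that it addresses had to be seen first.

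The balance of minor and major arms also differed in other pairs of genotypes. Over 80 precursors the median minor minus major log2 difference was -0.33 in tm1563 against the ME line (18 positive, 62 negative, sign test across precursors adjusted p = 4.89e-06) and -0.21 in the SH line against wild type (27 positive, 53 negative, adjusted p = 0.00974). It was -0.15 in tm1563 against wild type (32 positive, 48 negative, adjusted p = 0.139), 0.18 in the ME line against wild type and 0.10 in tm1563 against the SH line (46 positive and 34 negative in each, adjusted p = 0.219), which did not pass. Precursors are not independent replicates. With the library as the unit (median log2 ratio per library, 3 against 3), the groups were fully separated in 5 of the 6 comparisons, tm1563 against wild type and the ME line against wild type included, each at an exact two-sided permutation p = 0.1, the smallest this design allows. The tm1563 and SH libraries overlapped (exact permutation p = 0.2).

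In wild-type library 1 fewer features were detected, 326 against 365 to 400 in the other 11 libraries. Fewer reads alone are argued against by 8 libraries with fewer reads and more features detected. A few abundant miRNAs taking more of its reads (the top 10 held 81.3%) are argued against as the whole cause: with reads outside the top 10 thinned to 1441770 per library, it still had 315 features, a difference of -31.6 from the lowest of the other 11. What set this library apart stays open, and no biological explanation was tested.

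Along the first principal component of the 12 libraries, which held 29.8% of the variance, the ME libraries lay at 9.29, 4.62 and 5.12 and the other 9 at -0.18 or below.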
